A study of Mus musculus with 3 samples.

How the data were processed

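The study used 3 2-colour arrays, per the labels, each hybridised with RNA of 13.5 dpc kidney in channel 1 and 10.5 dpc metanephric mesenchyme in channel 2, with no common reference. The tissue was microdissected from CD1 mouse embryos of both sexes, pooled, and the RNA was amplified before labelling, per the labels. The array carried the Compugen mouse oligo library, in which an oligo stands for a transcript. Images were read with ImaGene 5.5, per the labels. The labels give print-tip loess within arrays and a normalization between arrays in R. They also describe a lowess curve of log ratio on log intensity, which took 20% of the data at each point and adjusted the control value, with control values under 10 set to 10. The order of these steps is not given in the sources used here.

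The values deposited by the authors are log2 ratios of the channels. The log base was taken from the values: as powers of 2 they are ratios of 3 decimals, to within 0.01 of the last decimal, for 99.8%, 99.7% and 99.8% of the values of arrays 1, 2 and 3. The lowest ratio is 0.01, held by 2 oligos on each array. The labels mention a dye swap without saying which array it concerns, and neither the dye of each RNA nor the numerator is given in the sources used here. The sign of each value is that of the deposited ratio. Whether the authors turned a swapped array is not given in the sources used here; every pair of arrays correlated above 0 across genes, and no sign was turned. Spot intensities were not used here, so background, saturation and dim spots could not be examined. No genome build is named, and no coordinates are given. Loess and scaling within an array set the middle of the ratios near 0, so a shift common to most genes would not be seen, and RNA amplification can alter ratios of single transcripts.

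Of 22702 spots, 881 control spots were left out, of which 856 had no value on any array. Of 21821 library oligos, 16658 had 1 gene symbol in the platform annotation, 137 had several and 5026 had none listed. Oligos with several or no symbols were kept under their own identifiers and named no gene. Of the oligos with 1 symbol, 15972 had an Entrez identifier found in the RefSeq gene table, which changed 0 symbols. A value on all 3 arrays was required, which left 21094 oligos. Of these, 16205 had 1 symbol and 4889 were unnamed. Oligos of the same symbol were averaged (1000 of 14746 symbols had more than 1 oligo), and 19635 genes were tested.

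Each gene's mean log2 ratio over the 3 arrays was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, then eBayes), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors are SDs over the 3 arrays unless stated. The moderated variance had a prior of 2.40 degrees of freedom and a prior SD of 0.333, and the median SE of a mean was 0.19 on the log2 scale. An exact sign-flip test of 1 gene on 3 arrays cannot go below a two-sided p of 0.25. Nothing in the sources used here says that the arrays came from separate tissue pools, so p-values of single genes measure only the spread between these arrays, which may be technical. The arrays were compared before they were averaged, and no pair held identical values. No batch is given in the sources used here.

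For gene lists, limma's camera was run with a preset correlation of 0.01 on lists with at least 3 measured members, with Benjamini-Hochberg adjustment over the 29 lists tested. In this form camera sets the genes of a list against the other genes. Its p rests on the spread across genes and on the preset correlation, and does not treat the 3 arrays as the replicates. A list's mean is the mean of its genes' log2 ratios, with the SD of the 3 array means. Camera was also run with an estimated correlation, which leaves it 2 residual degrees of freedom; 0 lists passed in that form. The test fry, which asks whether the genes of a list move one way on balance without setting them against other genes, was run beside it. Its adjusted p was 0.0329 for extracellular matrix, 0.0282 for renal stroma, 0.0329 for nephron progenitors, 0.0473 for erythroid genes, 0.0552 for muscle and 0.144 for gut. Of the lists that camera did not pass, fry passed ureteric bud (adjusted p = 0.0215), glycolysis (0.0329, but 0.271 without Slc2a1, which is at the floor), embryonic globins (0.0326, with Hbb-bh1 at -3.95 carrying a list whose other 2 genes stood at -0.21 and -0.062) and neural genes (0.0461).

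The 30 lists were fixed before the data were examined, as were the tests of the report and the alternatives, except those named as added. They were the nephron progenitor, ureteric bud, early nephron, podocyte, tubule and stroma lists of the kidney, extracellular matrix, epithelial adhesion and mesenchymal identity, and markers of endothelium, red cells, embryonic and adult globins, macrophages, smooth muscle, somite and skeletal muscle, neural cells, gut and liver, and gonad, adrenal and germ cells. The rest were proliferation, cell cycle inhibitors, ribosomal proteins, oxidative phosphorylation, glycolysis, Hox genes, imprinted genes, insulin-like growth factor binding, Wnt signalling, solute carriers, and immediate early and heat shock genes. Only 1 of 6 adult globins was measured, so that list was not tested. Of 17 erythroid genes measured, 5 were also in another list.

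Genes were named by a rule fixed before the data were examined. With under 5 genes past the threshold on a side, it took the 8 genes of the smallest p on that side with the same sign on all 3 arrays, leaving out symbols that are clone or prediction identifiers. It added up to 4 members of each list past the threshold or, where none passed, the 2 of the smallest p, and 11 kidney genes named in any case. This gave 71 genes. A further 46 were chosen after their values were seen, mainly members that passed when adjusted over their list alone. That adjustment does not correct for the number of lists, and its rate of passes in random lists was not computed. It serves to pick out members within a list and is no call over all genes.

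The alternatives left out each array in turn, centred each array on its median, scaled the arrays to equal median absolute deviation (limma's median absolute value scaling), quantile-normalized them, accepted genes with values on 2 arrays, tested each oligo on its own, used robust eBayes or array weights, and left out 83 oligos at an exact 0 or a repeated extreme. A dye term that takes array 3 as the opposite orientation, fry without Slc2a1 and the neural list without Sox2 were added after the data were seen. The fit was tested on simulated data of 19635 genes with 200 changed genes in 5 simulations. It recovered 0%, 52.4%, 84.4% and 90.8% of genes changed by log2 1, 2, 3 and 4, with 26 false calls among 595, and found a list of 20 genes shifted by 0.5 in 5 of 5 simulations. Of simulated unshifted lists, 1.7% had a p under 0.05. The simulated genes were drawn independently of each other, with no pair of arrays more alike than another. These rates may therefore not hold for lists of correlated genes or for the deposited arrays. Tables were handled with pandas 2.3.3, list-wise adjustment used statsmodels 0.14.6 and plots were drawn with matplotlib 3.10.9.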

Results

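The data were 3 2-colour oligonucleotide arrays, each of which set RNA of 13.5 dpc (days post coitum) mouse kidney directly against RNA of 10.5 dpc metanephric mesenchyme. The metanephric mesenchyme is the embryonic tissue that meets the ureteric bud and gives rise to the nephrons of the permanent kidney, and by 13.5 dpc the kidney holds branching collecting ducts, early nephrons and stroma. All 3 arrays belonged to 1 group, and each gave 1 deposited log2 ratio per oligo. Of 21821 library oligos, 21433, 21459 and 21477 had a value on arrays 1, 2 and 3, and 21094 had one on all 3. The number of arrays limits the precision. The median log2 ratio was 0.0014 on array 1, 0.030 on array 2 and 0.0014 on array 3. The sources used here do not give which RNA was the numerator or which dye each carried, so genes are placed on the positive or the negative side of the deposited ratio, and a positive sign is not read as higher in the kidney.

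The comparison asked which genes differ in RNA level between the early mesenchyme and the kidney that forms with it. On the positive side the genes with the smallest p included Cdh16, the kidney-specific cadherin of tubular epithelium, at a mean log2 ratio of 3.31 ± 0.48 (SD, n = 3 arrays), a 9.89-fold difference. Dcn, the matrix proteoglycan decorin, stood at 2.15 ± 0.26, and Crym, a thyroid hormone-binding protein, at 2.02 ± 0.20. On the negative side, Hbb-bh1, an embryonic beta-like globin, stood at -3.95 ± 0.32, a 15.4-fold difference. Klf1, the transcription factor of red-cell precursors, stood at -3.02 ± 0.29, an 8.11-fold difference, and Ermap, an erythroblast membrane protein, at -2.61 ± 0.27. The same sign on all 3 arrays was a condition of their selection and is no separate evidence. None of these genes passed the test over all genes (limma, Benjamini-Hochberg adjusted p = 0.107 for each).

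The other genes of the same selection on the positive side were Sel1l3 at 2.86 ± 0.081, the interferon-inducible Ifi27 at 2.65 ± 0.35, the potassium channel subunit Kcns1 at 2.57 ± 0.28, the lipocalin Lcn5 at 2.38 ± 0.24 and the LIM-domain cofactor Fhl2 at 1.93 ± 0.14 (mean log2 ratio ± SD, n = 3). On the negative side they were the co-chaperone Stip1 at -2.68 ± 0.35, the homeobox gene Nkx2-3 at -2.39 ± 0.043, the GDNF-family receptor Gfra3 at -2.27 ± 0.24 and Car2, a carbonic anhydrase of red cells and other tissues, at -2.17 ± 0.23. All 9 were likewise selected for the same sign on all 3 arrays, and all had a limma adjusted p of 0.107. Slc2a1, the glucose transporter GLUT1, was the only gene of 19635 to pass an adjusted p of 0.05 (limma, adjusted p = 0.00819), and 0 genes passed on the positive side. Its deposited ratio was 0.01 on all 3 arrays, the lowest ratio in the table (log2 -6.64). The call ended without any 1 of the arrays (limma adjusted p from 0.144 to 0.376), and 0 genes passed in those fits. Its mean and its SD of 0 were unchanged there, so these losses do not show that 1 array carried the call. It also ended with the median SD of the 20 genes of the next largest mean in place of its own SD (limma adjusted p = 0.106).

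At an unadjusted p under 0.05, limma gave 3304 of 19635 genes, of which 1766 were on the positive and 1538 on the negative side. Chance alone gives 982 if the arrays are independent, and turning the sign of array 3 still left 1221. The same sign on all 3 arrays was seen for 8117 genes, or 41.3% of those tested, where independent arrays give 25% by chance. Arrays 1 and 2 alone shared a sign for 69.8% of genes, so 25% is too low a baseline if these arrays share a bias. A mean log2 ratio of at least 1 in size was found for 1047 genes. Of these, 424 were positive and 475 negative on all 3 arrays.

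**Figure D1:**
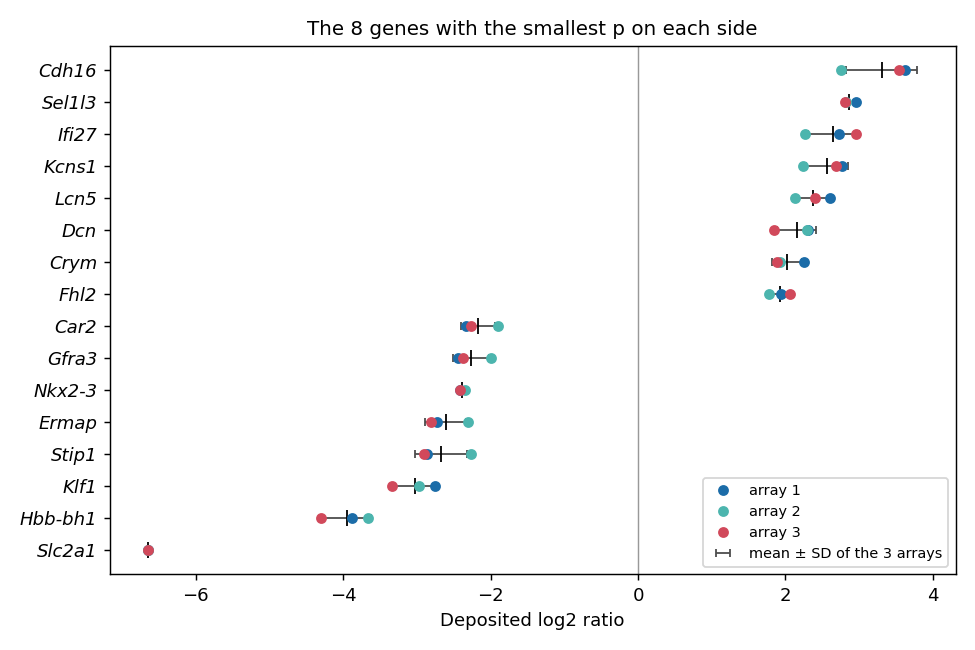
Deposited log2 ratio (horizontal axis) of the 8 genes with the smallest p on the positive side and the 8 on the negative side, among genes of the same sign on all 3 arrays. Points are the 3 arrays, and the bar is their mean ± SD; Cdh16 lies at 3.31 and Hbb-bh1 at -3.95, and Slc2a1 has the floor ratio on every array.

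Genes of the extracellular matrix lay together on the positive side. Of 34 measured members 25 had a positive mean, and the list mean was 0.55 ± 0.12 (log2, SD of the 3 array means; camera adjusted p = 6.71e-05, and 0.539 with an estimated correlation). Lama4, a laminin chain, stood at 2.22 ± 0.30, the collagen chains Col6a1 and Col1a1 at 1.71 ± 0.70 and 1.19 ± 0.29, and Sparc, a collagen-binding glycoprotein, at 1.59 ± 0.33. Fibronectin, Fn1, stood on the other side at -0.39 ± 0.17. Over all genes 0 members passed limma, 16 had an unadjusted p under 0.05, and 11 passed when adjusted over the list alone, all of them positive: Dcn, Lama4, Sparc, Bgn, Lamb1, Col1a1, Col6a1, Nid1, Col5a2, Fbln5 and Nid2. Here and in the lists below, adjustment over a list alone does not correct for the number of lists.

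Markers of the renal stroma, the interstitial cells around the nephrons, shifted the same way. The mean of 18 genes was 0.46 ± 0.062, and 14 were positive (camera adjusted p = 0.00604, and 0.539 with an estimated correlation). Foxd1, the transcription factor that marks stromal progenitors, stood at 0.72 ± 0.28, Meis2 at 0.77 ± 0.26, Snai2 at 0.76 ± 0.24, and Penk, which encodes proenkephalin, at 1.78 ± 0.98. Limma passed 0 members over all genes, 6 had an unadjusted p under 0.05, and 5 passed when adjusted over the list alone, namely these 4 and Dcn. Dcn and Lum belong to both the stromal and the matrix list, so the lists are not independent. With each oligo tested on its own the stromal call ended (mean 0.32, adjusted p = 0.0581).

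Genes of the metanephric mesenchyme and nephron progenitors were also shifted to the positive side, with a mean of 0.40 ± 0.094 over 20 genes, 15 of them positive (camera adjusted p = 0.00816, and 0.539 with an estimated correlation). Wt1, a transcription factor of the mesenchyme and later of podocytes, stood at 1.84 ± 0.27 and Cited1, a marker of cap mesenchyme, at 1.42 ± 0.23. Six2, which maintains nephron progenitors, stood at 0.78 ± 0.096, and Gdnf, the ligand that induces ureteric bud outgrowth, at 0.68 ± 0.25. Osr1, a transcription factor of the intermediate mesoderm, lay on the opposite side at -0.57 ± 0.067. These 5 genes and Crym were the 6 that passed when adjusted over the list alone; 7 members had an unadjusted p under 0.05 and 0 passed limma over all genes. Among other genes of early kidney development in this list, Pax2 stood at 0.29 ± 0.30, Eya1 at 0.27 ± 0.35, Cd24a at 0.42 ± 0.41 and Cdh11 at 0.15 ± 0.23, and none of these 4 passed either adjustment. Single arrays carried much of these means, which without replicate 2 were 0.12 for Pax2, 0.071 for Eya1 and 0.22 for Cd24a, and without replicate 3 were 0.023 for Cdh11. Without replicate 3 the call ended (mean 0.35, adjusted p = 0.127).

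Lists of the structures that form as the kidney differentiates had positive means, and none passed the camera test as fixed beforehand. Genes of the early nephron had a mean of 0.25 ± 0.19 over 23 genes (adjusted p = 0.146, and 0.0412 without replicate 2), with Wnt4, the signal for the mesenchyme-to-epithelium transition, at 1.84 ± 0.13, and the Notch-pathway genes Heyl and Hey1 at 1.72 ± 0.36 and 1.45 ± 0.40. These 3 passed when adjusted over the list alone. Lhx1, required for nephron formation, had arrays of opposite sign and a mean of 0.071 ± 0.99, the sign of which depended on the processing. The podocyte list had a mean of 0.24 ± 0.046 over 16 genes (adjusted p = 0.0841), and only Tcf21 passed over the list alone, at 1.57 ± 0.26. Nphs1, which encodes nephrin, stood at 0.17 ± 0.23, Podxl at -0.19 ± 0.19 and Foxc2 at 0.69 ± 0.33. On arrays 1, 2 and 3 Nphs1 had 0.099, -0.022 and 0.43, and Podxl -0.18, -0.38 and -0.0087. Maturing tubule genes had a mean of 0.29 ± 0.10 over 18 genes (adjusted p = 0.134), and 3 passed over the list alone: Cdh16, Clu at 1.54 ± 0.37 and, on the negative side, the endocytic receptor Cubn at -1.49 ± 0.47. Lrp2, the receptor megalin, stood at 0.37 ± 0.080. Ureteric bud and collecting duct genes had a mean of 0.24 ± 0.056 over 23 genes (adjusted p = 0.108). In that list 5 genes passed when adjusted over it alone, with Agtr2 at 1.56 ± 0.31, Etv4 at 1.54 ± 0.35, Calb1 at 1.07 ± 0.083 and Gata3 at 1.02 ± 0.11 on the positive side and the keratin Krt19 at -1.03 ± 0.21 on the negative side. Ret, the receptor for Gdnf on the bud tip, stood at -0.19 ± 0.26, with -0.35, -0.33 and 0.11 on arrays 1, 2 and 3. Limma passed 0 members of these 4 lists over all genes; at an unadjusted p under 0.05 there were 4 early nephron, 3 podocyte, 5 tubule and 8 ureteric bud genes.

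**Figure D2:**
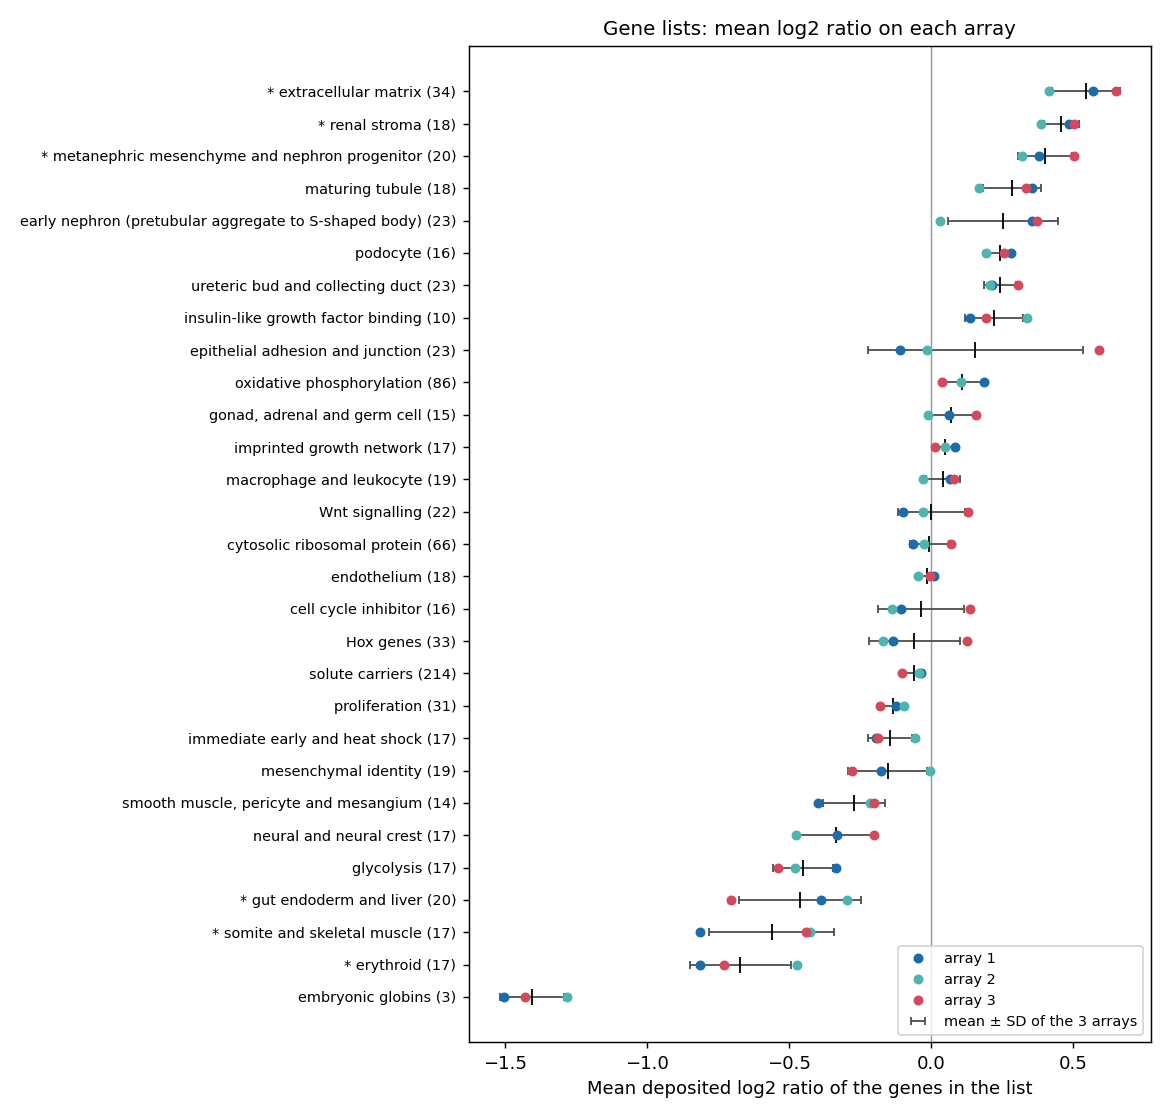
Mean deposited log2 ratio (horizontal axis) of each gene list on each of the 3 arrays (points), with the mean ± SD of the arrays (bar) and the number of measured genes in parentheses. Stars mark the 6 lists past a camera adjusted p of 0.05; extracellular matrix has the highest mean of these at 0.55 and the erythroid list the lowest at -0.67.

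Red-cell genes lay on the negative side. The mean of 17 erythroid genes was -0.67 ± 0.18, their median was -0.21, and 13 were negative (camera adjusted p = 0.00739, and 0.539 with an estimated correlation). Besides Hbb-bh1, Klf1 and Car2, Alas2, the heme synthesis enzyme of red cells, passed when adjusted over the list alone, at -1.20 ± 0.24. Limma passed 0 of the 17 over all genes, 6 had an unadjusted p under 0.05, and 4 passed over the list alone. The other globins stood nearer 0, with Hba-x at -0.21 ± 0.15, Hbb-y at -0.062 ± 0.26, a mean that turned positive in 2 alternative settings, and the adult globin Hba-a1 at -0.084 ± 0.13. On arrays 1, 2 and 3 Hba-x had -0.35, -0.046 and -0.22, and Hba-a1 -0.099, -0.21 and 0.057. The 3 embryonic globins had a mean of -1.41 ± 0.11 and did not pass (adjusted p = 0.0656, and 0.0470 with array weights), with 1 of them, Hbb-bh1, past limma's test when adjusted over the list alone, and Hba-a1 was the only adult globin measured. Without replicate 3 the erythroid call ended (mean -0.64, adjusted p = 0.0649).

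Somite and skeletal muscle genes also lay on the negative side, with a mean of -0.56 ± 0.22 over 17 genes, 13 of them negative (camera adjusted p = 0.00600, and 0.539 with an estimated correlation). Skeletal actin, Acta1, stood at -1.98 ± 0.45, the somite transcription factor Tcf15 at -1.08 ± 0.11, and the muscle genes Myl1 and Myf6 at -0.97 ± 0.14 and -0.94 ± 0.49. Of the 17, limma passed 0 over all genes, 9 had an unadjusted p under 0.05, and 7 passed when adjusted over the list alone: those 4, Tnnc1, Des and, on the positive side, the somite homeobox gene Uncx at 1.11 ± 0.40. With each oligo tested on its own the mean was -0.34 and the call ended (adjusted p = 0.0701).

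Gut endoderm and liver genes had a mean of -0.46 ± 0.21 over 20 genes, 15 of them negative (camera adjusted p = 0.00600, and 0.539 with an estimated correlation). The secreted liver and yolk sac proteins Ttr, Afp and Apoa1 stood at -2.24 ± 1.00, -1.44 ± 0.13 and -1.14 ± 0.23, and transferrin, Trf, at -0.996 ± 0.448, while albumin, Alb, stood at 0.87 ± 0.57. The first 4 of these were the 4 that passed when adjusted over the list alone, where 8 members had an unadjusted p under 0.05 and 0 passed limma over all genes. Without replicate 3 the call ended (mean -0.34, adjusted p = 0.127). Neural and neural crest genes had a mean of -0.34 ± 0.14 over 17 genes and did not pass camera (adjusted p = 0.0687), though they passed with array weights (mean -0.38, adjusted p = 0.0443). Without replicate 1, or with genes on 2 arrays admitted, Sox2 alone joined the list and it passed at a mean of -0.51 (adjusted p = 0.0105 and 0.0207). With Sox2 left out the means were -0.34 and -0.34 (adjusted p = 0.0490 and 0.0700). Isl1, a transcription factor of motor and sensory neurons, stood at -1.71 ± 0.37 and Gap43, a growth-cone protein, at -0.86 ± 0.042. These were the 2 that passed over the list alone, with 6 at an unadjusted p under 0.05 and 0 past limma over all genes.

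Genes of mesenchymal identity went both ways. The list mean was -0.15 ± 0.14 over 19 genes, or -0.090 without replicate 3 (camera adjusted p = 0.649), and 8 members passed when adjusted over the list alone, 4 on each side, with 0 past limma over all genes and 9 at an unadjusted p under 0.05. Twist1, Twist2, Prrx1 and Msx1, transcription factors of limb and craniofacial mesenchyme, stood at -1.57 ± 0.13, -1.15 ± 0.019, -1.28 ± 0.17 and -1.41 ± 0.64. Foxc1, Foxc2, Snai2 and Meox2 lay between 0.55 and 0.76.

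Lists of other cell types and of epithelial adhesion did not pass the camera test. Endothelial genes had a mean of -0.013 ± 0.029 over 18 genes (adjusted p = 0.889), with Ramp2 at 0.64 ± 0.14 and Cd34 at -0.86 ± 0.47. Macrophage and leukocyte genes had a mean of 0.041 ± 0.059 over 19 genes, from 0.021 to 0.075 with 1 array left out (adjusted p = 0.722), with the integrin Itgam at -0.80 ± 0.24 and the Fc receptor chain Fcer1g at 0.67 ± 0.46. For Fcer1g array 1 stood apart, at 1.20 against 0.47 and 0.35 on arrays 2 and 3. Smooth muscle, pericyte and mesangial genes had a mean of -0.27 ± 0.11 over 14 genes (adjusted p = 0.264), where Tagln, an actin-binding protein of smooth muscle, stood at -1.90 ± 0.25 and Tpm1 at -1.18 ± 0.69. For Tpm1 array 1 had -1.98, against -0.73 and -0.83 on arrays 2 and 3. Genes of gonad, adrenal and germ cells had a mean of 0.071 ± 0.084 over 15 genes, from 0.027 without replicate 3 to 0.11 without replicate 2 (adjusted p = 0.649), with the germ cell helicase Ddx4 at -1.34 ± 0.21 and the steroidogenic enzyme Hsd3b1 at 0.91 ± 0.32. Epithelial adhesion genes had a mean of 0.16 ± 0.38 over 23 genes (adjusted p = 0.0841), and their array means were -0.11, -0.014 and 0.59. Without replicate 3 the mean was -0.062 (adjusted p = 0.947), and the list passed without replicate 1 (0.29, adjusted p = 0.0165). Tjp1 and Spint2 of that list stood at 0.71 ± 0.23 and 0.67 ± 0.23. When adjusted over each list alone, Tagln and Ddx4 passed and 0 members of the other 3 lists did; over all genes limma passed 0 in these 5 lists, against 2, 2, 3, 5 and 8 at an unadjusted p under 0.05.

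Among growth regulators, the insulin-like growth factor binding proteins went both ways. Igfbp7 stood at 2.65 ± 0.61 and Igfbp6 at 1.34 ± 0.56, against -0.89 ± 0.50 for Igfbp3 and -0.61 ± 0.21 for Igfbp4, and these 4 of 10 genes passed when adjusted over the list alone. The list mean was 0.22 ± 0.10, while its median of -0.15 and the direction of the camera test were negative (adjusted p = 0.807). In the imprinted growth network, H19 stood at 0.92 ± 0.24, Dlk1 at -1.09 ± 0.22 and Ndn at -0.81 ± 0.20, which with Dcn made 4 of 17 genes past the adjustment over the list alone; the mean was 0.049 ± 0.034, or 0.032 without replicate 1, and the median of -0.0065 and the camera direction were negative (adjusted p = 0.807). Of the Wnt signalling genes, Frzb, a secreted Wnt antagonist, stood at -1.91 ± 0.20, Wnt6 at -0.95 ± 0.19 and the receptor Fzd2 at 0.67 ± 0.11, and these and Wnt4 were the 4 of 22 that passed over the list alone, with a list mean of 0.00042 ± 0.12, the sign of which depended on the processing (adjusted p = 0.649). Among 33 Hox genes, which set position along the body axis, Hoxd13 stood at -2.13 ± 0.52, Hoxb6 at 1.33 ± 0.26 and Hoxa5 at 1.78 ± 0.57. These 3 passed over the list alone, and the list mean of -0.059 ± 0.16 had the opposite sign to its median of 0.058 and to the camera direction (adjusted p = 0.649). Over all genes limma passed 0 members of these 4 lists, against 4, 4, 6 and 12 at an unadjusted p under 0.05.

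Proliferation genes had a mean of -0.13 ± 0.043 over 31 genes (camera adjusted p = 0.287). The replication genes Cdc45 and Mcm6 stood at -1.39 ± 0.36 and -1.24 ± 0.28 and the proliferation marker Mki67 on the other side at 0.78 ± 0.062, and these 3 passed when adjusted over the list alone. Cell cycle inhibitors had a mean of -0.036 ± 0.15 over 16 genes, which turned positive without replicate 1 or 2 and with a dye term and was -0.12 without replicate 3 (adjusted p = 0.649), with the pocket protein Rbl2 at 1.02 ± 0.39 and Btg2 at 0.82 ± 0.32. Oxidative phosphorylation genes had a mean of 0.11 ± 0.074 over 86 genes, or 0.072 without replicate 1 (adjusted p = 0.0819, and 0.0443 with array weights), and 2 passed over the list alone, Uqcrb at 1.69 ± 0.22 and Ndufa4 at 1.45 ± 0.14. Glycolysis genes had a mean of -0.45 ± 0.10 over 17 genes and a median of -0.11 (adjusted p = 0.108). Slc2a1 at the floor carried that mean, which was -0.065 over the other 16 genes (adjusted p = 0.392 with the floor oligos left out). In that list 2 genes passed over the list alone, Slc2a1 and the hypoxia-responsive Bnip3, the second at -0.74 ± 0.079. Cytosolic ribosomal protein genes had a mean of -0.0065 ± 0.068 over 66 genes, the sign of which depended on the processing (adjusted p = 0.649), with Rpl23 at 0.75 ± 0.16 and Rps25 at 0.54 ± 0.064. Solute carriers had a mean of -0.061 ± 0.036 over 214 genes, or -0.031 without Slc2a1 (adjusted p = 0.807), of which Slc2a1 and the zinc transporter Slc39a7, at -2.22 ± 0.35, passed over the list alone. Immediate early and heat shock genes had a mean of -0.15 ± 0.078 over 17 genes (adjusted p = 0.393), with Ier2 at -1.70 ± 0.36, which passed over the list alone, and Hsph1 at -0.28 ± 0.082. In these 7 lists limma passed Slc2a1 over all genes and 0 others, and 9 proliferation, 4 inhibitor, 13 oxidative phosphorylation, 4 glycolysis, 4 ribosomal, 39 solute carrier and 1 immediate early genes had an unadjusted p under 0.05. Such counts, here and in the lists above, are to be read against 3304 of all 19635 genes. The solute carrier (39 of 214), oxidative phosphorylation (13 of 86), early nephron (4 of 23) and podocyte (3 of 16) counts lie near that share. The ribosomal (4 of 66), endothelial (2 of 18), macrophage (2 of 19) and immediate early (1 of 17) counts lie below it. No difference between the share of a list and that of all genes was tested.

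The arrays differed in how well they matched each other across genes, which are not independent replicates. Arrays 1 and 2 correlated at a Pearson r of 0.46 and a Spearman rho of 0.52 over 19635 genes, and 69.8% of genes had the same sign. Array 3 correlated with array 1 at 0.17 (rho 0.19) and with array 2 at 0.16 (rho 0.17), with 57.2% and 55.7% of genes of the same sign. The matrix, stromal and nephron progenitor lists had positive means on all 3 arrays, from 0.42 to 0.65, from 0.39 to 0.50 and from 0.32 to 0.50. The erythroid, muscle and gut lists had negative means on all 3, from -0.81 to -0.47, from -0.81 to -0.43 and from -0.70 to -0.30. As these lists were called on the same arrays, a shared sign is no separate evidence. Uncalled lists such as ureteric bud, podocyte, tubule and neural genes also kept their sign on all 3, while epithelial adhesion, ribosomal protein and Hox genes did not.

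**Figure D3:**
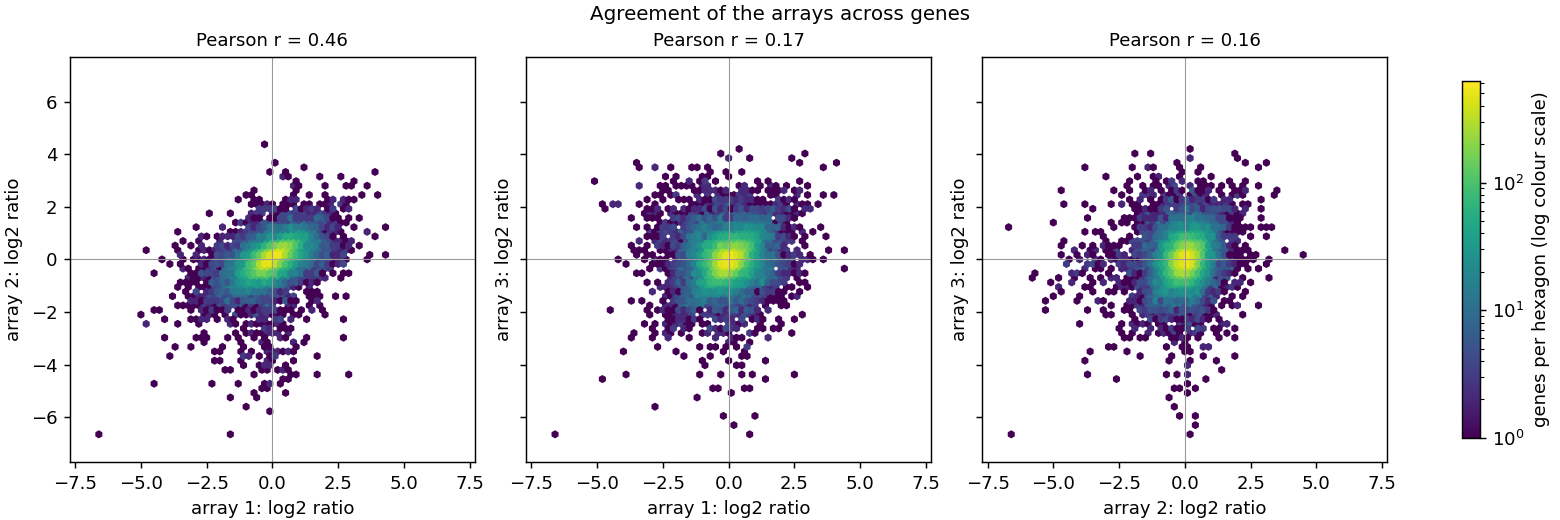
Deposited log2 ratio of each gene on one array (horizontal axis) against another (vertical axis), for the 3 pairs of arrays, with colour giving the number of genes per hexagon on a log scale. Arrays 1 and 2 correlate at a Pearson r of 0.46 across genes, against 0.17 and 0.16 for the pairs with array 3.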

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

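The tests of array 3 and of the sign patterns were chosen after the results were seen, and the test of Slc2a1 was written down before its result.

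Oligos without a value on all 3 arrays stayed out of the main tests and entered only alternatives that needed 2 arrays, and 2 of them held large ratios on both arrays that measured them. Sox2, a transcription factor of neural and foregut progenitors, had a mean log2 ratio of -3.46 (-3.13 on array 2 and -3.79 on array 3). Arg1, the urea cycle arginase, had -3.86 (-3.38 on array 1 and -4.35 on array 3). Among the control spots, 21 whose names begin with YIR held a value on at least 1 array, with medians of -0.30 (14 spots), -0.53 (21 spots) and 0.022 (20 spots) on arrays 1, 2 and 3, while 0 of 562 spots named blank held one.

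Arrays 1 and 2 varied together across genes more than either did with array 3 (Pearson r 0.46 against 0.17 and 0.16, across genes, which are not independent replicates). Independent noise on array 3 was excluded as the whole cause, since it adds no covariance: the covariance of arrays 1 and 2 exceeded the mean of the other pairs by 0.130 (95% bootstrap interval 0.118 to 0.143). Weaker ratios on array 3 were not seen in the lists, as the means of the 29 lists on array 3 had a slope of 1.08 (0.929 to 1.23) on those of arrays 1 and 2, where the covariances call for 0.385. Weaker ratios over all genes were not excluded, since lists share members, Slc2a1 is at the floor on every array and unnamed oligos enter no list. A dye bias with array 3 in the opposite orientation may account for part of the pattern: medians of 44 blocks of 500 library numbers correlated at 0.87 between arrays 1 and 2 but at -0.85 and -0.77 with array 3, yet subtracting them lowered the covariance difference over oligos only from 0.133 to 0.109 (0.0982 to 0.120). For the rest, a dye bias of single genes and a different tissue collection for array 3 cannot be told apart, since the orientation is not given in the sources used here, and no biological explanation was tested. If array 3 had the opposite orientation, part of any dye bias would remain in the mean log2 ratios, since 2 arrays outweigh 1.

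The call of Slc2a1 rested on a spread of 0, which the floor ratio gives on all 3 arrays. With the median SD of the 20 genes of the next largest mean, 0.89, its limma adjusted p was 0.106, so the zero spread is a candidate explanation for the call. The log2 ratio of -6.64 is the floor and not a measured level. Whether the spot failed or was dim in a channel stays open, since intensities were not used here, and no biological explanation was tested.

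Turning the sign of 1 array at a time gives 4 sign patterns, which are too few for a share under 0.05. The deposited signs gave 1 gene and 6 lists past the threshold, the only 1 of the 4 patterns to give as many in either case, and the highest of the others was 0 genes and 0 lists. At an unadjusted limma p under 0.05 the deposited signs gave 3304 genes, against 265, 284 and 1221 with array 1, 2 or 3 turned.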

How the results depend on the processing

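The dye term with array 3 as the opposite orientation, fry without Slc2a1 (adjusted p = 0.271 for glycolysis and 0.974 for solute carriers) and the neural list without Sox2 were chosen after seeing the data, and all other alternatives before. The count of genes past the threshold, 1, which is Slc2a1 on the negative side, fell to 0 without any 1 array (range 0 to 0), with arrays scaled to equal median absolute deviation, with oligos at an exact 0 or a repeated extreme left out (which removes it) and with the dye term. In these settings limma gave from 1686 to 4085 genes at an unadjusted p under 0.05, and the positive count was 0 in every setting. Slc2a1's adjusted p ran from 0.0046 with array weights to 0.376 without replicate 2. Its ratio is the same on every array, so the losses with 1 array left out do not show that 1 array carried the call.

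Lists past camera numbered 6, from 3 to 8 with 1 array left out (3 without replicate 3), from 4 (each oligo on its own) to 9 (array weights) in the other settings, and 0 with an estimated correlation. In that form the 6 means were by construction as reported, 0.55 for matrix, 0.46 for stroma, 0.40 for nephron progenitors, -0.67 for erythroid, -0.56 for muscle and -0.46 for gut. The test then has 2 residual degrees of freedom. The estimated correlation was -0.0077 for matrix, -0.057 for stroma and -0.031 for nephron progenitors, all below the preset 0.01. For these lists the loss therefore came with the fewer degrees of freedom and not with a higher correlation. It was above the preset for erythroid (0.129), muscle (0.025) and gut (0.115) genes, where the 2 were not separated. With 1 array left out the means ran from 0.35 to 0.44 for nephron progenitors, from -0.77 to -0.60 for erythroid genes and from -0.55 to -0.34 for gut. All 3 calls ended without replicate 3 (adjusted p = 0.127, 0.0649 and 0.127), where their means were 0.35, -0.64 and -0.34. With each oligo on its own, stroma had 0.32 (adjusted p = 0.0581) and muscle -0.34 (adjusted p = 0.0701). The cause of these losses was not tested. Extracellular matrix kept its call in every setting but the estimated correlation.

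Of the comparisons of called lists with an alternative, 67 kept the call and 11 lost it, and 0 turned direction. Among uncalled lists 284 were alike. In 8 comparisons such a list passed: neural genes without replicate 1 (-0.51) and with genes on 2 arrays (-0.51), where Sox2 alone was added (-0.34 in both without it, adjusted p = 0.0490 and 0.0700), and with array weights (-0.38), epithelial adhesion without replicate 1 (0.29) and with the dye term (0.26), early nephron without replicate 2 (0.37), and embryonic globins (-1.38) and oxidative phosphorylation (0.12) with array weights. In 7 the list turned the direction of the test: endothelium without replicate 2 and with the dye term (-0.011), ribosomal proteins and insulin-like growth factor binding without replicate 1, and Hox genes, Wnt signalling and solute carriers without replicate 3. With 1 array left out their means ran from -0.025 to 0.0025 for endothelium, from -0.047 to 0.022 for ribosomal proteins, from 0.16 to 0.26 for insulin-like growth factor binding, from -0.17 to -0.0038 for Hox genes, from -0.064 to 0.051 for Wnt signalling and from -0.073 to -0.041 for solute carriers. In 11 more comparisons, of 4 uncalled lists (epithelial adhesion, -0.062 without replicate 3, cell cycle inhibitors, ribosomal proteins and Wnt signalling), the mean changed sign and the direction of the test did not. Among named genes 1391 comparisons were alike, 5 lost the call (Slc2a1) and 7 turned sign: Lhx1 without replicate 1 or 3 (range from -0.24 to 0.64 with 1 array left out), with equal median absolute deviation (-0.0093), quantile normalization (-0.0087) and array weights (-0.19), and Hbb-y without replicate 1 (from -0.21 to 0.046 with 1 array left out) and with the dye term (0.011). The cause was not tested. Signal over background could not be examined, and the number of arrays limits the precision.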

Other observations

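The gene families by symbol and the tests of red cells and of the direction of the ratio were chosen after the values were seen; the direction itself was named as a question before the data were examined.

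Small nucleolar RNA host genes (symbols beginning Snhg) lay on the positive side, with 10 of 10 members positive and a mean log2 ratio of 0.39 ± 0.072 (SD of 3 array means). The organic anion transporters (Slco) had 10 of 10 positive and a mean of 0.38 ± 0.071. Proteasome regulatory subunits (Psmd) had 10 of 14 negative and a mean of -0.42 ± 0.10. Of 239 families formed by symbol, 0 passed camera after Benjamini-Hochberg adjustment (adjusted p = 0.124 for Snhg, 0.258 for Slco and 0.429 for Psmd), and at an unadjusted limma p under 0.05 there were 4, 2 and 6 of their genes.

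A hypothesis for the direction of the ratio is that the 13.5 dpc kidney is the numerator. The 57 measured members of the podocyte, tubule and ureteric bud lists, structures that the kidney forms after the mesenchyme stage, had a median log2 ratio of 0.13, at the 98.8th percentile of 10000 random gene sets of that size, with 39 positive and 18 negative and medians of 0.16, 0.077 and 0.34 on arrays 1, 2 and 3. The nephron progenitor list, which marks the mesenchyme but also cells that the kidney keeps, lay further on the same side (median 0.28, mean 0.40, camera adjusted p = 0.00816, and 0.539 with an estimated correlation). The series title names the mesenchyme before the kidney, while the labels put the kidney in channel 1. These values do not settle the direction, which stays open.

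The negative shift of the erythroid list may reflect more red cells in one of the RNAs. That would move all abundant globins alike only if the red cells of both ages held the same globins. The sources used here do not give the globins of red cells at either age. The 4 measured globins therefore cannot test red-cell content. Their median was -0.15, with Hbb-bh1 at -3.95, Hba-x at -0.21, Hba-a1 at -0.084 and Hbb-y at -0.062, and the last 2 had arrays of both signs. Bright spots can saturate and press ratios toward 0, which could not be examined without intensities, so red-cell content and a change in Hbb-bh1 and its regulators cannot be told apart. Of the 17 measured erythroid genes, 5 are also in another list, 4 of them the globins. No biological explanation was tested.

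Genes of the same sign on arrays 1 and 2 were set against array 3, and differences between the shares were not tested. Of 119 genes with a mean of arrays 1 and 2 at or below -2, 48.7% had the same sign on array 3 and 41 had the opposite sign by at least 1 in size. Of 44 genes with that mean at or above 2, 93.2% had the same sign and 0 were opposite by that much. For means from 1 to 2 in size the shares were 60.2% of 665 low and 68.6% of 634 high genes, and from 0.5 to 1 they were 60.7% of 1760 and 64.8% of 2086. The oligos with no gene name had an r of 0.36 between arrays 1 and 2 but 0.019 and 0.022 with array 3, against 0.50, 0.22 and 0.21 for named genes, across genes, which are not independent replicates.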
